A study of Mus musculus with 23 samples.

How the data were processed

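Total RNA of 23 mouse bone marrow samples was extracted with Trizol, fragmented and biotinylated with a WT Terminal Labeling Kit, and hybridised to 1-colour arrays, per the labels' protocols. The deposited values are gene-level probe set signals on a log2 scale. The labels name Transcriptome Analysis Console, without a version, per the submitters' processing notes, and background correction, summarization and normalization are not stated. The deposited log2 values ran from 3.65 to 14.2, array medians from 6.06 to 6.2 and 75th percentiles from 8.1 to 8.31, so the arrays had been brought to a common scale while their quantiles differed. The number of arrays limits the precision.

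Groups followed the sample titles: 10 Pax5+/- leukemic (samples 1 to 10), 7 Pax5+/- preleukemic (11 to 13 and 21 to 24), 3 WT leukemic (14, 15 and 17) and 3 WT preleukemic samples (18 to 20). A further WT leukemia, sample 16, was not used here. Mouse numbers in the labels give each Pax5+/- sample a mouse of its own. Titles call the leukemic samples pro-B cells and descriptions call them leukemic marrow, and neither states a sort. Sex and strain are not stated, and Xist and Eif2s3y levels were used to count samples of each sex.

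Of 28944 probe sets, 21789 carried 1 gene symbol. Those with several symbols (1621) or none (5534) were left out. For each of 19938 symbols the probe set of highest mean was used. A gene was tested if its value exceeded the 30th percentile of its array on at least 3 arrays, which left 15542 and removed 4396. Gene order along the genome came from the GRCm38.p6 RefSeq annotation and was used only to find neighbouring genes, with no coordinates.

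Before the data were examined, the groups, tests, gene lists, alternatives and rule for named genes had been fixed. All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The contrasts were leukemic against preleukemic in each genotype, Pax5+/- against WT at each stage, and the interaction. Folds are 2 raised to the fitted log2 difference, and standard errors are on the log2 scale. Pax5 levels and cell type list means were compared by exact two-sided permutation of the samples.

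The 30 gene lists held 19 programmes and 11 sets of cell type markers. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. A repeat estimated the correlation per list, and fry tested whether a list's genes moved one way on balance. Member counts were given over all genes tested and adjusted over the list alone. Of the cell type lists, neutrophil (9 of 14), stroma (7 of 10), megakaryocyte (5 of 7), plasma cell (5 of 9), mature B cell (5 of 8), plasmacytoid dendritic cell (5 of 8), monocyte (5 of 14), erythroid (3 of 8), T cell (3 of 11), NK cell (2 of 9) and progenitor markers (2 of 7) had members above the array median in every preleukemic sample.

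Named genes were Pax5, the 10 genes of largest rise and 10 of largest fall among those that passed, without predicted genes or receptor segments, and up to 4 passing members of smallest p per list, from which 2 or 3 examples were taken. Where fewer than 5 passed in a direction, the 5 of smallest p were also eligible, and for the interaction the 5 of smallest p in each direction were taken. Genes outside the rule are said to have been chosen after their values were seen.

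Alternatives were no filter, a filter at the 50th percentile, eBayes without trend or with robust priors, array weights, quantile normalization, median centring, only the 2 groups of a contrast, all probe sets, Xist or the first component of the marker genes as a covariate, the letter of the mouse number as a random block, and leaving out each sample in turn. Samples 15, 17 and 20 together, and Pax5+/- leukemias 2, 6 and 7 together, were left out after their markers had been seen. The fits were tested on simulated data with the real genes and group sizes, in which 200 of 15542 genes were changed. Each gene varied independently around a single mean with a single pooled SD for all groups. Correlated genes, unequal spread between groups and outlying samples were thus not simulated, and calls on the real data can be less reliable. At a log2 change of 1 the share of changed genes recovered was 95.5% for Pax5+/- leukemic against preleukemic, 82.1% for WT leukemic against preleukemic, 89.6% for the genotypes before leukemia, 83.6% for the genotypes in leukemia and 83.6% for the interaction. For each contrast 5 to 11 unchanged genes were called. Figures were drawn with matplotlib 3.10.9.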

Results

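Gene expression was measured in marrow of mice that had received 2 Gy of irradiation at 2 months of age, with 1 array per sample. Pax5+/- mice lack 1 copy of Pax5, the transcription factor that commits progenitors to the B cell lineage. The samples were leukemic marrow of 10 Pax5+/- and 3 wild-type (WT) mice, and preleukemic pro-B and pre-B cells taken 3 weeks after the dose from 7 Pax5+/- and 3 WT mice. Array medians lay between 6.06 and 6.2 on the log2 scale, and the number of arrays limits the precision. The first principal component held 59.5% of the variance and separated the stages. Leukemic samples scored 13.57 to 41.96, preleukemic samples -54.9 to -16.51, and the samples nearest the opposite stage were Pax5+/- leukemic sample 7 and WT preleukemic sample 20.

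Pax5 itself was lower in leukemia. Its mean log2 level was 11.39 ± 0.08 (SD, n = 7) in Pax5+/- preleukemic cells and 8.52 ± 1.23 (SD, n = 10) in Pax5+/- leukemias, a 7.28-fold fall (exact two-sided permutation p = 0.000411). In 9 of the 10 leukemias the level was below every preleukemic sample, and in leukemia 7 it was 11.42, inside their range of 11.31 to 11.53. In WT mice the mean was 11.81 ± 0.32 (SD, n = 3) before leukemia and 9.26 ± 2.55 (SD, n = 3) in leukemia. The WT leukemias held 10.68, 6.32 and 10.78, all below the WT preleukemic samples, and the exact p was 0.1, the smallest that 3 samples against 3 allow. The limma adjusted p for WT was 0.0335, and it was 0.28 without WT leukemia 15. Before leukemia, Pax5+/- cells held 1.34-fold less Pax5 than WT cells (exact permutation p = 0.0167, n = 7 and n = 3, and p = 0.0556 without WT sample 18 or 19), while the limma test across all groups gave an adjusted p of 0.965. Between the leukemias of the genotypes the difference of -0.74 on the log2 scale was smaller than the spread within either group (exact permutation p = 0.49, n = 10 and n = 3). It was -2.21 without WT leukemia 15 (exact permutation p = 0.0455), -0.03 without 14 and 0.02 without 17. Whether the Pax5 probes lie in the deleted part of the gene is not known, so the level is not a check of the genotypes.

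**Figure D1:**
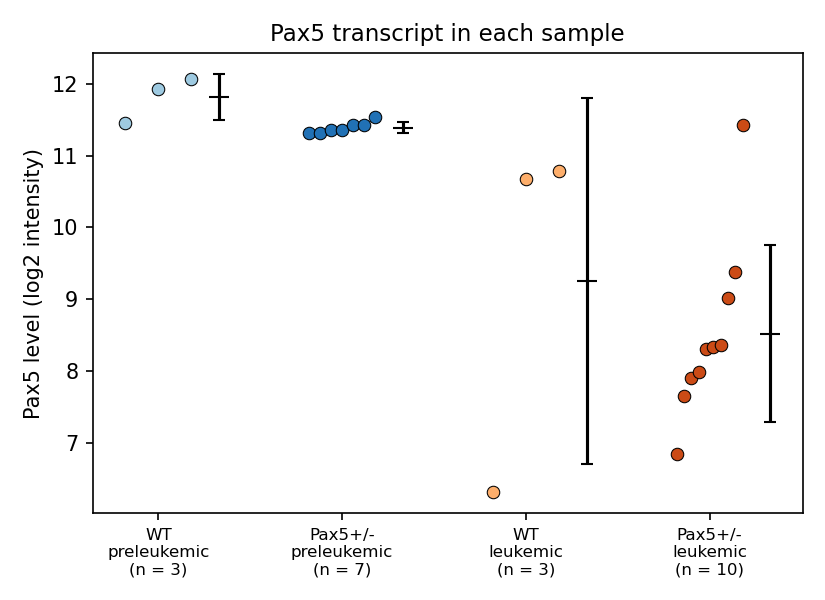
Pax5 level (log2 intensity, vertical axis) in each of the 23 samples by group, points sorted by value within a group, with the group mean and SD as a black bar beside them. Preleukemic samples sit between 11.31 and 12.06, and 9 of 10 Pax5+/- leukemias and all 3 WT leukemias sit below every preleukemic sample.

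The Pax5+/- leukemias were compared with Pax5+/- preleukemic cells, which asks what separates the leukemia from irradiated B cell precursors. Titles name pro-B cells for the leukemias but pro-B and pre-B cells for the preleukemic samples. Time after the dose is labelled for the preleukemic samples only, and all mice were irradiated. In both genotypes leukemia thus cannot be told apart from B cell stage, time after the dose or age. Fcrla, an Fc receptor-like protein of B cells, fell 45.1-fold (SE 0.15 on the log2 scale, n = 10 and n = 7, limma adjusted p = 8e-17). Ikzf3, which encodes the B cell transcription factor Aiolos, fell 32.3-fold, and the metallopeptidase gene Cpm fell 32.2-fold. Ppbp, a platelet chemokine gene, rose 76.7-fold (SE 0.29, adjusted p = 3.7e-13), Jchain, the joining chain of secreted antibodies, rose 37.1-fold, and Flt3, the tyrosine kinase receptor of early progenitors, rose 31.3-fold. Of 15542 genes tested, 10034 (64.6%) passed an adjusted p of 0.05, 4357 higher and 5677 lower, and 1542 of them differed over 2-fold, 1068 higher and 474 lower. With a filter at the 50th percentile the balance turned, with 4109 higher and 3684 lower. Of 30 gene lists, 14 passed with the preset correlation between genes and 0 with an estimated one.

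The other genes of largest rise were Mrgpra1 (49.2-fold), the potassium channel gene Kcnma1 (39.9-fold), Emb (31.5-fold), ccdc198 (23.1-fold), Il18r1, a subunit of the interleukin-18 receptor (22.6-fold), Atp8b4 (21.5-fold) and Thbs1, thrombospondin 1 (21.4-fold). Those of largest fall were Otub2 (26.3-fold), Reln (21.7-fold), Atp1b1 (21.0-fold), Polm (19.1-fold), Cd2 (14.3-fold), Trib2 (13.5-fold) and the B cell surface protein Cd72 (13.4-fold). For 16 of the 76 passing genes named in this comparison the lower group mean lay below every array median, so background limits the size of their folds and their order. These were Mrgpra1, Kcnma1, Jchain, Emb, Flt3, ccdc198, Il18r1, Atp8b4, Thbs1, Pf4 and Poll among the rises and Otub2, Reln, Polm, Cplx2 and Ms4a1 among the falls. With 1 sample left out the fold of Kcnma1 ran from 32.4 to 62.7. Of 11 measured immunoglobulin gene segments, 9 fell and 0 rose, with a median log2 fold change of -1.78. Of 4 T cell receptor segments, 2 fell and 0 rose, with log2 fold changes from -0.195 to 1.142 and a median of -0.072, so the falls were small.

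Targets of PAX5 moved in both directions. Of 17 measured PAX5-activated genes, 15 fell and 0 rose, with a median log2 fold change of -2.31 (camera adjusted p = 9.4e-08, and adjusted p = 0.0951 with an estimated correlation). Siglecg, an inhibitory lectin of B cells, fell by 3.57 on the log2 scale, Bach2 by 2.91 and Cplx2 by 2.31. Lef1 fell by 3.14, Foxo1 by 2.08 and Ebf1 by 1.49, 3 regulators of early B cells chosen after their values were seen. Of 13 PAX5-repressed genes, 9 rose and 2 fell, with a median of 2.01 (adjusted p = 0.00188, and adjusted p = 0.286 with an estimated correlation). Besides Flt3, Emb and Jchain these included the progenitor regulator Lmo2, up 5.95-fold, and the adaptor Grap2, up 4.04-fold. Monocyte, plasma cell and progenitor marker lists share members with this list, among them Csf1r, Jchain and Flt3.

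Genes of B cell stages fell more often than they rose, while lists of pre-B cell receptor and interleukin-7 signalling did not pass. Of all genes that passed in this comparison 43.4% were higher, so falls were the more common change. Of 18 small pre-B to immature B cell genes, 12 fell and 0 rose, such as Irf4 (7.51-fold), Ms4a1, which encodes CD20 (6.88-fold), and Spib (5.33-fold). The list median was -1.07 (adjusted p = 0.00134, and adjusted p = 0.0951 with an estimated correlation). Of 17 pro-B cell genes, 9 fell and 2 rose (median -0.75, adjusted p = 0.0224, and adjusted p = 0.524 with an estimated correlation). The chromatin remodeller gene Smarca4 fell 3.5-fold and Lig4 fell 4.76-fold, while Bok rose 1.62-fold. The recombinase genes Rag1 and Rag2, chosen after their values were seen, had log2 fold changes of -2.54 and -2.81, both passing. Of 15 pre-B cell receptor signalling genes, 6 fell and 3 rose and the list did not pass (adjusted p = 0.361), with the kinase Syk down 3.48-fold, Pik3ap1 down 3.22-fold and Plcg2 up 1.61-fold. Of 18 interleukin-7 and JAK-STAT genes, 5 rose and 6 fell (list adjusted p = 0.946). Among them the survival gene Bcl2 rose 6.47-fold and its relatives Bcl2l1 and Mcl1 fell 4.81-fold and 1.92-fold.

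Growth and division genes rose. Of 21 MYC target and ribosome biogenesis genes, 20 rose and 0 fell, with a median of 0.99 (adjusted p = 1.01e-10, and adjusted p = 0.286 with an estimated correlation). Spermidine synthase Srm rose 5.98-fold, Mybbp1a 3.64-fold and the pyrimidine synthesis gene Cad 3.02-fold. Myc, chosen after its value was seen, rose by 3.62 on the log2 scale. All 21 mitosis genes rose (median 1.30, adjusted p = 1.7e-07, and adjusted p = 0.521 with an estimated correlation), such as the kinase genes Plk1 (3.94-fold) and Aurka (3.03-fold). Of 24 DNA replication genes, 17 rose and 0 fell (median 0.60, adjusted p = 0.00148, and adjusted p = 0.701 with an estimated correlation), with thymidylate synthase Tyms up 3.21-fold. Of 13 glycolysis genes, 9 rose and 0 fell (median 0.73, adjusted p = 2.74e-04, and adjusted p = 0.336 with an estimated correlation), with Pdk1 up 4.11-fold and lactate dehydrogenase Ldha up 2.67-fold.

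DNA repair genes did not move as a block. Of 19 homologous recombination genes, 17 rose and 1 fell (median 0.68, adjusted p = 4.02e-05, and adjusted p = 0.521 with an estimated correlation), with Brca2 up 2.22-fold and the exonuclease Exo1 up 2.1-fold. Of 17 DNA damage checkpoint genes, 12 rose and 3 fell (median 0.66, adjusted p = 0.00475, and adjusted p = 0.524 with an estimated correlation). The kinase Atr rose 1.64-fold and Timeless 1.76-fold, and Rad9a fell 1.7-fold. All 11 end joining genes changed, 5 higher and 6 lower (list adjusted p = 0.946). Polm, a polymerase of end joining, and the ligase Lig4 fell, and the related polymerase Poll rose 1.74-fold. Of 15 base excision and mismatch repair genes, 8 rose and 4 fell (list adjusted p = 0.57). The endonuclease Apex1 rose 3.82-fold, the glycosylase Neil1 fell 12.1-fold, Msh3 fell 2.36-fold and Xrcc1, a scaffold of single-strand break repair, fell 2.08-fold. Of 26 p53 target genes, 7 rose and 6 fell (list adjusted p = 0.946). Btg2, an inhibitor of proliferation, fell 8.58-fold and the ribonucleotide reductase subunit Rrm2b fell 6.81-fold.

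Among B cell leukemia driver and suppressor genes, 5 of 19 rose and 10 fell (list adjusted p = 0.458). The tumour suppressors Btg1 and Rb1 fell 4.07-fold and 3.11-fold, and Etv6 rose 2.42-fold. Of 20 inflammation and NF-kB targets, 1 rose and 11 fell (list adjusted p = 0.133), with Tnfaip3 down 4.07-fold and Tnf up 3.85-fold. Of 20 interferon response genes, 7 rose and 2 fell (list adjusted p = 0.176), Rtp4 by 4.51-fold among the rises. Of 8 MHC class II genes, 1 rose and 1 fell (list adjusted p = 0.895). Among lists that did not pass, interleukin-7, MHC class II and NK cell lists had medians of opposite sign to their test, and p53, base excision and mismatch repair, NK and plasma cell lists had medians of opposite sign to their means.

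Markers of megakaryocytes, monocytes, neutrophils and stroma were higher in the same leukemias, and markers of other cell types were not all so. All 7 megakaryocyte markers rose, with a median of 1.84 (adjusted p = 2.25e-04, and adjusted p = 0.453 with an estimated correlation), including Pf4 (11.7-fold) and Gp9 (7.55-fold). Monocyte and macrophage markers rose in 11 of 14 and fell in 0 (median 1.71, adjusted p = 2.33e-04, and adjusted p = 0.516 with an estimated correlation), with complement C1qb up 9.35-fold and Vcam1 up 8.39-fold. Neutrophil markers rose in 11 of 14 and fell in 0 (median 1.95, adjusted p = 0.0108, and adjusted p = 0.701 with an estimated correlation), with Mmp9 up 9.88-fold. Stroma and endothelium markers rose in 8 of 10 and fell in 1 (median 1.24, adjusted p = 9.42e-04, and adjusted p = 0.336 with an estimated correlation), with Sparc up 16.0-fold. Lists that did not pass were T cell (4 of 11 rose, adjusted p = 0.18), NK cell (1 of 9 rose, adjusted p = 0.908), plasma cell (2 of 9 rose and 4 fell, adjusted p = 0.661), mature B cell (1 of 8 rose and 4 fell, adjusted p = 0.361), progenitor (3 of 7 rose and 2 fell, adjusted p = 0.5), plasmacytoid dendritic cell (4 of 8 rose, adjusted p = 0.343) and erythroid markers (1 of 8 rose and 1 fell, adjusted p = 0.908). The mean level of a list per sample differed for 8 of 11 cell type lists by exact permutation. It was higher on the log2 scale for megakaryocyte (2.60, adjusted p = 0.000189), neutrophil (1.77, 0.0103), monocyte (1.54, 0.000283), stroma (1.48, 0.000189), progenitor (1.03, 0.000189) and T cell markers (0.52, 0.00622), and lower for mature B cell (-0.64, 0.00204) and erythroid markers (-0.38, 0.00509). Plasmacytoid dendritic cell (0.57, adjusted p = 0.0731), plasma cell (0.10, 0.24) and NK cell means (0.06, 0.746) did not pass. With the median over the members in place of the mean 6 lists differed, and the erythroid (-0.005, adjusted p = 0.956) and T cell lists (0.17, 0.399) did not.

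With the first component of these markers, without the plasma cell and mature B cell lists, as a covariate, 3444 genes passed in place of 10034. Of the 3444, 3035 were shared with the main fit, and 2049 were higher and 1395 lower. Megakaryocyte, stroma and progenitor means separated the stages completely (exact permutation p = 5.14e-05, the smallest these samples allow). Such a covariate can remove stage differences whatever their cause. The lower count thus cannot tell other cells from changes within the leukemic cells. Counts adjusted over the list alone equalled the counts given, except for 1 rise in the small pre-B list, 9 rises in base excision and mismatch repair, 6 in interferon response, 3 in T cell markers and 0 in erythroid markers.

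**Figure D2:**
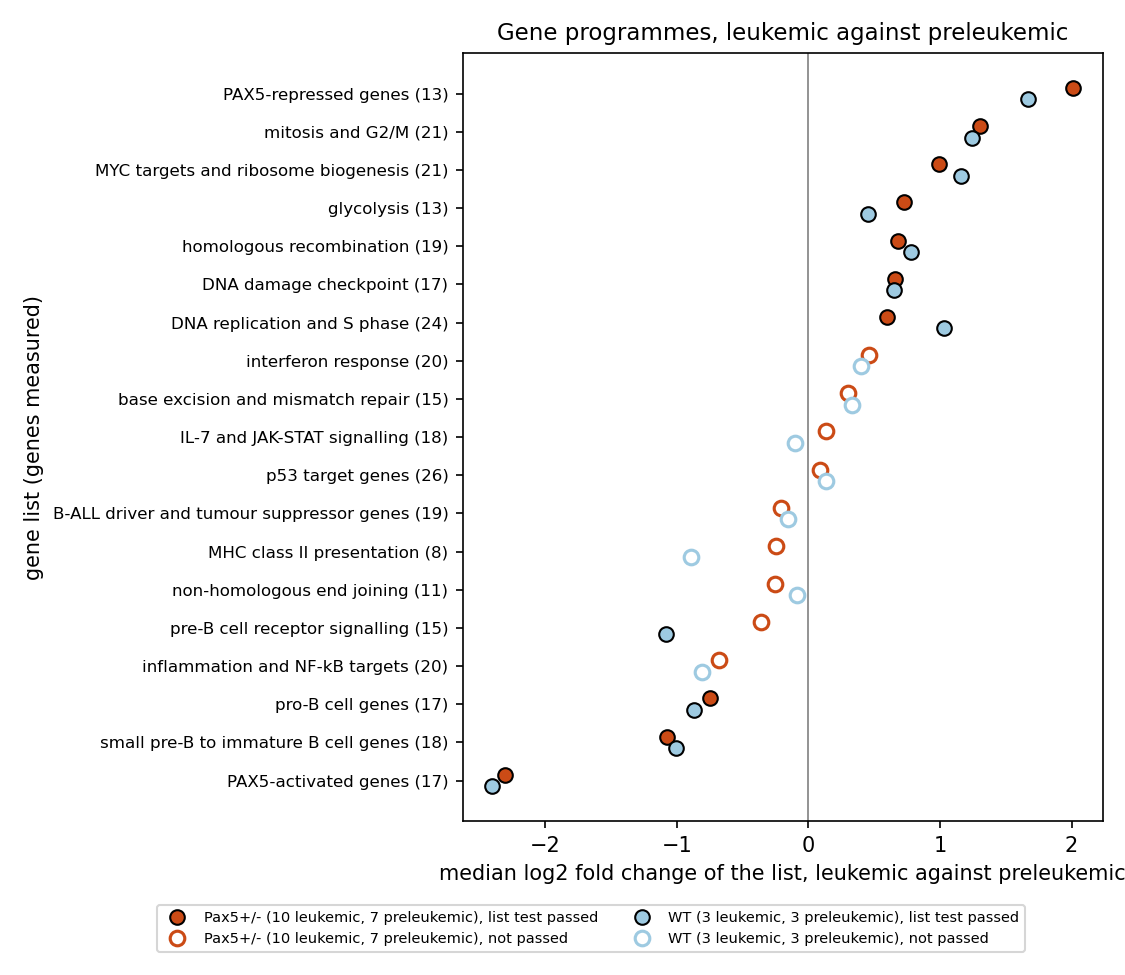
Median log2 fold change, leukemic against preleukemic (horizontal axis), of each of 19 gene programme lists (vertical axis, genes measured in brackets), in Pax5+/- and WT mice. Filled points passed the list test with the preset correlation, and PAX5-activated genes had the lowest medians, -2.31 and -2.40.

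In WT mice the same comparison of leukemia with preleukemic cells rested on 3 samples against 3. The genes that fell most included several of the same B cell genes, Fcrla (34.9-fold, SE 0.25 on the log2 scale, limma adjusted p = 7e-12), Ikzf3 (29.5-fold), Reln (22.2-fold), Siglecg (21.9-fold), Cpm (21.0-fold), Polm (19.6-fold), Atp1b1 (18.3-fold) and Fcmr, the receptor of IgM (18.2-fold), together with the stem cell receptor Lgr5 (18.1-fold). Those that rose most included Ppbp (98.1-fold, SE 0.48, adjusted p = 3.7e-09), Mrgpra1, Jchain (39.9-fold), ccdc198 (31.1-fold), Thbs1 (3.83 on the log2 scale) and Pf4 (13.6-fold). Serping1 (23.1-fold), Ctsk (14.4-fold) and Bgn (14.3-fold) were among them too. In all, 5780 genes passed, 2783 higher and 2997 lower, 1426 of them over 2-fold. Xist had a mean log2 level of 12.21 in WT leukemias and 5.30 in WT preleukemic samples (adjusted p = 0.0284), and the Y-linked gene Eif2s3y 4.45 and 9.17 (adjusted p = 0.0357). The lower mean of each lay below every array median, as it did for Mrgpra1, Jchain, ccdc198, Serping1, Ctsk, Bgn, Reln, Polm and Lgr5, which limits the size of their folds. Xist exceeded Eif2s3y in all 3 WT leukemias and in 0 of 3 WT preleukemic samples, so stage and sex of the mice coincided in WT. Among Pax5+/- mice it did so in 5 of 10 leukemic and 3 of 7 preleukemic samples.

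The 14 lists that passed in Pax5+/- mice also passed in WT mice, in the same direction. Of lists that passed in neither, MHC class II, NK cell and plasmacytoid dendritic cell lists tested upward in Pax5+/- and downward in WT mice, and end joining and plasma cell lists the other way. The interleukin-7 and JAK-STAT median was 0.13 in Pax5+/- and -0.10 in WT mice. Of 17 PAX5-activated genes 15 fell, 16 adjusted over the list alone (median -2.40, camera adjusted p = 1.38e-10, and adjusted p = 0.0265 with an estimated correlation), with Bach2 down 11.9-fold. Of 18 small pre-B to immature B cell genes 9 fell (adjusted p = 2.6e-04, and adjusted p = 0.0421 with an estimated correlation). Pro-B cell genes fell in 10 of 17 and rose in 1 (adjusted p = 0.0018, and adjusted p = 0.3 with an estimated correlation), with Rag1 down 11.8-fold. Pre-B cell receptor signalling genes fell in 9 of 15 and rose in 1 (adjusted p = 0.0059, and adjusted p = 0.3 with an estimated correlation), with Pik3ap1 down 4.63-fold. PAX5-repressed genes rose in 7 of 13 and fell in 1 (adjusted p = 0.00313, and adjusted p = 0.291 with an estimated correlation), with Flt3 up 12.6-fold and Csf1r, the receptor of macrophage colony-stimulating factor, up 11.4-fold. With 1 sample left out, folds moved by over 1.5 times for 6 of 33 named genes, to 7.21 to 21.3 for Csf1r, 9.25 to 23.3 for Flt3, 27.3 to 83.9 for Jchain, 22.9 to 47.8 for Ikzf3, 6.41 to 17.6 for Rag1 and 2.11 to 9.92 for Pax5.

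Growth, homologous recombination and checkpoint lists rose in WT, and other repair lists did not pass. All 21 MYC target and ribosome biogenesis genes rose (adjusted p = 1.79e-13, and adjusted p = 0.218 with an estimated correlation), with Srm up 7.11-fold. DNA replication genes rose in 21 of 24 and fell in 0 (median 1.03, adjusted p = 2.56e-09, and adjusted p = 0.3 with an estimated correlation), with the helicase subunit Mcm6 up 2.8-fold. Mitosis genes rose in 19 of 21, 20 adjusted over the list alone (adjusted p = 1.54e-07, and adjusted p = 0.339 with an estimated correlation). Homologous recombination genes rose in 15 of 19, 17 adjusted over the list alone, and fell in 1 (adjusted p = 4.61e-06, and adjusted p = 0.3 with an estimated correlation). Checkpoint genes rose in 11 of 17, 12 adjusted over the list alone, and fell in 1 (adjusted p = 1.95e-04, and adjusted p = 0.3 with an estimated correlation), with the kinase Chek1 up 3.26-fold. Glycolysis genes rose in 6 of 13, 7 adjusted over the list alone (adjusted p = 2.6e-04, and adjusted p = 0.3 with an estimated correlation). The p53 target list (6 rose and 6 fell of 26, adjusted p = 0.799), end joining (4 and 4 of 11, 0.913), base excision and mismatch repair (6 and 3 of 15, 0.196), interleukin-7 and JAK-STAT (2 and 5 of 18, 0.799), interferon (1 and 0 of 20, 0.166), MHC class II (0 and 1 of 8, 0.211), leukemia drivers (4 and 7 of 19, 0.196) and inflammation (1 and 6 of 20, 0.0594) did not pass. Adjusted over the list alone, p53 targets rose in 7, end joining genes in 5, base excision and mismatch repair genes in 7, interleukin-7 genes in 3 and interferon genes in 0. Medians differed in sign from the mean for interleukin-7 and p53 lists, and from the test for end joining. Within these lists Neil1 fell 10.7-fold, Btg2 7.67-fold and Rrm2b 5.0-fold, and Apex1 rose 3.47-fold.

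Among cell type lists in WT, megakaryocyte markers rose in 6 of 7 (adjusted p = 3.41e-05, and adjusted p = 0.3 with an estimated correlation), stroma markers in 7 of 10 with 1 lower (adjusted p = 3.01e-04, and adjusted p = 0.291 with an estimated correlation), monocyte markers in 6 of 14 (adjusted p = 6.44e-04, and adjusted p = 0.339 with an estimated correlation), neutrophil markers in 1 of 14 (adjusted p = 0.014, and adjusted p = 0.672 with an estimated correlation) and erythroid markers in 5 of 8 (adjusted p = 0.00673, and adjusted p = 0.401 with an estimated correlation). T cell, NK cell, plasma cell, mature B cell, progenitor and plasmacytoid dendritic cell lists did not pass, with adjusted p of 0.624, 0.49, 0.799, 0.139, 0.799 and 0.624. Adjusted over the list alone, 7 megakaryocyte, 8 stroma, 0 neutrophil and 1 mature B cell markers rose. The neutrophil marker mean was 10.57 in WT preleukemic sample 20, against 6.65 in sample 18 and 6.69 in sample 19. It ran from 9.36 to 10.31 in the WT leukemias. The low count of neutrophil markers that rose thus cannot be read as a difference from Pax5+/- mice. NK, monocyte and erythroid means of sample 20 were also the highest of its group. Without WT leukemia 17 the erythroid (adjusted p = 0.0687) and neutrophil lists (0.0575) no longer passed, nor did the neutrophil list without WT sample 18 (0.1) or 19 (0.131). List means per sample differed for 0 of 11 lists, where the smallest exact p that 3 samples against 3 allow is 0.1. The count of genes fell to 3794 without WT preleukemic sample 19 and 3828 without sample 18, to 3537 with only these 2 groups in the fit, and to 2353 with the marker component as a covariate.

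Fold changes of the stages were alike in the genotypes. Across the 15542 genes, which are not independent replicates, they correlated with r = 0.904 and rho = 0.861, with no sample shared. In both genotypes 2529 genes rose, where independent lists would share 780.2, 2671 fell, where they would share 1094.7, and 7 passed in opposite directions.

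Before leukemia, 3 weeks after the same dose, Pax5+/- cells were compared with WT cells, which asks what the genotype changes in irradiated B cell precursors. Slc1a5, a glutamine transporter, fell 8.54-fold in Pax5+/- cells (SE 0.24 on the log2 scale, n = 7 and n = 3, limma adjusted p = 1.7e-07), and Edaradd, an adaptor of ectodysplasin receptor signalling, fell 3.89-fold (SE 0.18, adjusted p = 1.5e-06). Ly86, which encodes MD-1, a partner of the B cell protein RP105, rose 3.74-fold (SE 0.27, adjusted p = 6.3e-04). Of 15542 genes 97 passed, 36 higher and 61 lower, and 31 differed over 2-fold, 6 higher and 25 lower. Other genes of largest fall were Apobec3, a cytidine deaminase that restricts retroviruses (5.8-fold), the NK cell receptor Klra8 (4.37-fold), Dock9, an exchange factor of Cdc42 (3.27-fold), Klhl14 (3.09-fold), Eps8l1 (2.98-fold), Tmc7 (2.85-fold), Lpcat2 (2.74-fold) and Pacs2 (2.69-fold). Other genes of largest rise were Stk38l (2.73-fold), Mcoln2 (2.64-fold), Gtse1 (2.31-fold), Gfod1 (2.12-fold), Prxl2c (2.05-fold), Cenpv (1.95-fold), Fmn2 and Oaf (1.92-fold each) and Ocel1 (1.89-fold). With each of the 10 samples left out in turn, Lpcat2 and Fmn2 lost their call in 9 of 10 runs, Prxl2c in 8, Ocel1 in 6, Gfod1 in 3 and Apobec3 in 1. The fold of Klra8 ran from 2.53 to 6.68. The lower mean of Klra8, Eps8l1, Tmc7 and Lpcat2 lay below every array median, which limits the size of their folds.

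In this comparison 1 DNA repair gene and 1 p53 target gene passed, both higher in Pax5+/- cells. Xrcc1 rose 1.64-fold (SE 0.14, adjusted p = 0.015), and without WT sample 18, 19 or 20 it no longer passed, with an adjusted p of up to 0.088. Xrcc1 lay in a run of 3 neighbouring genes along the genome that all passed, each higher in Pax5+/- cells, by 0.62 to 0.87 on the log2 scale. Gtse1, which acts on p53 in the later cell cycle, had an adjusted p of 0.022, and of up to 0.24 without WT sample 18 or 19. The base excision and mismatch repair list shifted upward (median 0.19, camera adjusted p = 0.00181, and adjusted p = 0.504 with an estimated correlation), with 1 of 15 members passing, 3 adjusted over the list alone. The DNA replication list shifted upward (median 0.36, adjusted p = 2.62e-08, and adjusted p = 0.634 with an estimated correlation), with 0 of 24 members passing, 1 adjusted over the list alone. The checkpoint list (median 0.15, adjusted p = 0.00974, and adjusted p = 0.702 with an estimated correlation) and the p53 target list (median 0.10, adjusted p = 0.0427, and adjusted p = 0.378 with an estimated correlation) shifted upward, with 0 of 17 and 1 of 26 members passing. Without WT sample 18 the base excision and mismatch repair list (adjusted p = 0.0573) and the checkpoint list (0.29) no longer passed, and without WT sample 19 the checkpoint (0.33) and p53 target lists (0.153) did not. The p53 target list also did not pass without WT sample 20 (0.105) or Pax5+/- sample 12 (0.0943) or 23 (0.0634). PAX5-activated genes had a median of -0.05 with 0 of 17 passing (list adjusted p = 0.8), and PAX5-repressed genes a median of -0.39 with 0 of 13 passing (0.182), 1 lower adjusted over the list alone.

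Of 11 marker lists of other cells, 4 were lower in the Pax5+/- preleukemic samples by the list test. NK cell markers (median -1.41, adjusted p = 1.39e-07, and adjusted p = 0.378 with an estimated correlation), neutrophil markers (median -1.39, adjusted p = 1.64e-04, and adjusted p = 0.702 with an estimated correlation), plasmacytoid dendritic cell markers (median -0.64, adjusted p = 0.00181, and adjusted p = 0.504 with an estimated correlation) and monocyte markers (median -0.30, adjusted p = 0.0151, and adjusted p = 0.707 with an estimated correlation) shifted downward, while only Klra8 passed among their members, and 3 NK markers and 1 plasmacytoid dendritic cell marker adjusted over the list alone. In WT preleukemic sample 20 the mean of the neutrophil markers was 10.57 against 6.65 and 6.69 in the other WT preleukemic samples, and that of the plasmacytoid dendritic cell markers 9.52 against 7.69 and 7.89. Its NK, monocyte and erythroid marker means were the highest of the group too. Without that sample the neutrophil list turned upward (adjusted p = 0.869), the plasmacytoid dendritic cell and monocyte lists no longer passed (0.869 each), the NK list stayed lower (0.00244) and 137 genes passed. List means per sample differed for 0 of 11 lists, with a smallest adjusted p of 0.0917, among them plasma cell markers, 0.17 higher in Pax5+/- cells (exact permutation p = 0.00833). Other lists that did not pass were pro-B (adjusted p = 0.681), small pre-B (0.8), pre-B cell receptor (0.42), interleukin-7 and JAK-STAT (0.57), homologous recombination (0.643), end joining (0.565), mitosis (0.271), MYC targets (0.779), glycolysis (0.0726), interferon (0.0726), MHC class II (0.334), leukemia drivers (0.528), inflammation (0.745), erythroid (0.232), T cell (0.271), plasma cell (0.0788), mature B cell (0.42), megakaryocyte (0.982), progenitor (0.145) and stroma markers (0.745), with 1 plasma cell marker higher adjusted over the list alone. The pro-B and MYC lists had medians of opposite sign to their tests. The gene count fell to 40 without WT sample 19, and rose to 444 with array weights and to 231 with only these groups in the fit.

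**Figure D3:**
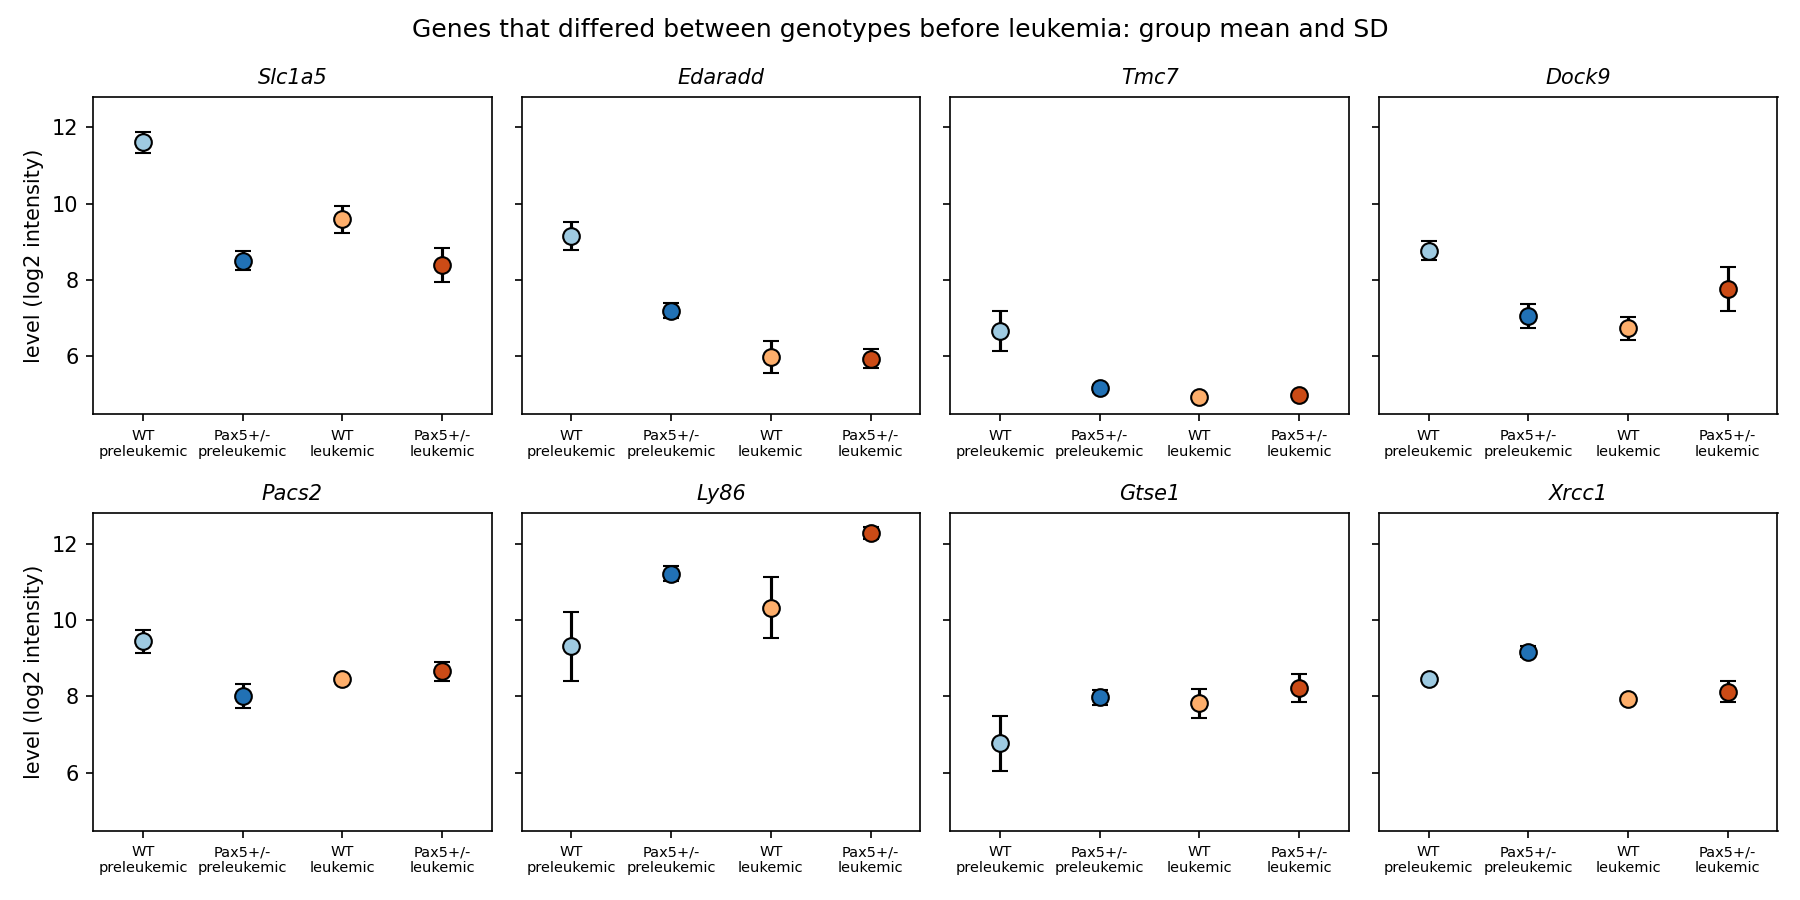
Mean level and SD (log2 intensity, vertical axis) of 8 genes that passed between Pax5+/- and WT preleukemic cells, in the 4 groups of 3, 7, 3 and 10 samples. Slc1a5 was 8.54-fold lower and Ly86 3.74-fold higher in Pax5+/- preleukemic cells, while Edaradd and Tmc7 lay at like levels in the leukemias of both genotypes.

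The leukemias of the genotypes were then compared with each other. Red blood cell genes were lower in the Pax5+/- leukemias. Car1, carbonic anhydrase 1, was 13.0-fold lower (SE 0.64 on the log2 scale, n = 10 and n = 3, limma adjusted p = 0.018) and Slc4a1, the anion exchanger of the red cell membrane, 8.87-fold lower (SE 0.64, adjusted p = 0.03). Rhag, Kel, Rhd and Ermap, which carry or accompany blood group antigens, were 7.68-fold, 6.55-fold, 4.54-fold and 4.09-fold lower, followed by Cldn13 (6.27-fold), the membrane skeleton genes Epb42 (4.8-fold) and Ank1 (3.57-fold), and the glycine transporter Slc6a9 (3.69-fold). The folds of all 10 moved by over 1.5 times with 1 sample left out, from 7.89 to 27.9 for Car1, 5.39 to 22.2 for Slc4a1 and 4.59 to 21.0 for Rhag. In Pax5+/- leukemias the means of Rhag, Kel, Cldn13, Epb42, Rhd, Ermap, Slc6a9 and Klf1 lay below every array median, which limits the size of their folds. Xist exceeded Eif2s3y in all 3 WT and in 5 of 10 Pax5+/- leukemias, so sex was not balanced between these groups. Of 15542 genes 53 passed, 49 lower and 4 higher. The 4 higher genes were Ly86 (3.88-fold, adjusted p = 0.0033), Gnb4 (3.34-fold, adjusted p = 0.015), Zfp740 (1.41-fold) and Rtl6 (1.39-fold), and the gene of next smallest p, Dalrd3, was 1.34-fold higher with an adjusted p of 0.052. Ly86 and Slc1a5 were the only genes that passed in the same direction between the genotypes before and in leukemia. Slc1a5, chosen after its value was seen, had a log2 fold change of -1.20 in leukemia.

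Erythroid markers fell in 3 of 8, and in 8 of 8 adjusted over the list alone, with a median of -1.94 (camera adjusted p = 2.44e-21, and adjusted p = 0.0148 with an estimated correlation). Klf1, the master regulator of red cell genes, was 2.05-fold lower (adjusted p = 0.015). The erythroid marker mean was 8.97 in WT leukemia 15 and 9.15 in WT leukemia 17, against 6.62 in WT leukemia 14 and 6.41 ± 0.23 (SD, n = 10) in Pax5+/- leukemias (exact permutation p = 0.00699, adjusted p = 0.0769 over 11 lists). Without WT leukemia 15, 0 genes passed, without WT leukemia 17, 5 passed, and without WT leukemia 14, 160 passed.

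Other lists that shifted between the leukemias lost their call with an estimated correlation. Pre-B cell receptor signalling (median 0.24, adjusted p = 7.37e-05, and adjusted p = 0.429 with an estimated correlation), pro-B cell genes (0.27, adjusted p = 0.0072, and adjusted p = 0.8 with an estimated correlation) and MHC class II genes (0.66, adjusted p = 0.0024, and adjusted p = 0.8 with an estimated correlation) were shifted upward in Pax5+/- leukemias. Neutrophil markers (-1.39, adjusted p = 6.89e-07, and adjusted p = 0.8 with an estimated correlation), NK cell markers (-0.93, adjusted p = 0.0072, and adjusted p = 0.8 with an estimated correlation), monocyte markers (-0.26, adjusted p = 0.0124), DNA replication (-0.15, adjusted p = 0.0024), MYC targets (-0.16, adjusted p = 0.0124) and interferon response genes (-0.19, adjusted p = 0.00834) were shifted downward, the last 4 with adjusted p = 0.856 with an estimated correlation. The mitosis list was shifted downward too (-0.18, adjusted p = 0.0349, and adjusted p = 0.898 with an estimated correlation). Several of these calls were lost or turned with single samples left out. Without WT leukemia 15 the interferon list passed in the upward direction (adjusted p = 3.19e-04), the NK list turned upward (0.595), and the pre-B cell receptor (0.068), pro-B (0.946), MHC class II (0.115), MYC (0.068) and mitosis lists (0.0883) no longer passed. Without WT leukemia 14 the DNA replication (0.107), MYC (0.773) and mitosis lists (0.449) did not pass, and without 17 the monocyte list (0.0679) did not. Among Pax5+/- leukemias, calls were lost without leukemia 7 for interferon (0.103) and monocyte lists (0.0627), without 9 for monocyte (0.0823), without 3 for MYC (0.19), and without 2, 4 or 6 for mitosis (0.0585, 0.192 and 0.159). Of all their members 0 passed over all genes, and adjusted over the list alone 3 pre-B cell receptor genes were higher, and 1 interferon gene and 1 monocyte marker lower. PAX5-activated (median 0.16, adjusted p = 0.194), PAX5-repressed (-0.03, 0.613) and small pre-B genes (0.04, 0.982), p53 targets (0.05, 0.699), homologous recombination (-0.06, 0.374), end joining (-0.02, 0.954), checkpoint (-0.03, 0.613) and base excision and mismatch repair genes (0.03, 0.613) did not pass. Interleukin-7 and JAK-STAT (adjusted p = 0.374), glycolysis (0.0653), leukemia driver (0.616), inflammation (0.194), T cell (0.699), plasma cell (0.411), mature B cell (0.964), megakaryocyte (0.374), progenitor (0.982), plasmacytoid dendritic cell (0.558) and stroma lists (0.954) did not pass either. Adjusted over the list alone, 1 interleukin-7 gene and 1 p53 target were lower. Medians differed in sign from the mean for small pre-B, interleukin-7, T cell, progenitor and stroma lists, and from the test for small pre-B, interleukin-7, end joining and stroma lists.

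The test of the interaction asked which genes changed differently between the stages in the genotypes. In all, 15 genes passed, each with a more positive change in Pax5+/- than in WT mice. This 1-sided direction was lost without WT leukemia 14, where 98 passed, 24 more positive and 74 more negative, and with array weights, where 82 passed, 50 more positive and 32 more negative. More negative genes also passed without WT sample 20 (7 of 36), without samples 15, 17 and 20 together (8 of 25) and in 7 other settings (1 or 2 each). The interaction is the genotype difference in leukemia minus that before it. All 15 genes had passed as lower in Pax5+/- cells before leukemia, against the same 3 WT samples, so their interaction and its direction largely restate that difference. Tmc7 fell by 1.73 on the log2 scale in WT and had a change of -0.17 in Pax5+/- mice, a difference of 1.56 (SE 0.17, limma adjusted p = 1e-04). Edaradd fell by 3.18 in WT and by 1.26 in Pax5+/- mice, a difference of 1.92 (SE 0.25, adjusted p = 9e-04). The differences of Col5a3, a fibrillar collagen gene, Dock9 and Pacs2 were 0.88, 2.75 and 1.62. Of genes with a more negative change in Pax5+/- mice 0 passed in limma, where 1118 genes had an unadjusted p under 0.05 in either direction. The nearest were Oaf (-1.09, adjusted p = 0.071), Prep (-0.57, 0.085), the heme synthesis gene Cpox (-1.44, 0.17), Cth (-0.48, 0.19) and Klf1 (-1.01, 0.19). The count ranged from 6 without WT preleukemic sample 19 to 98 without WT leukemia 14.

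**Figure D4:**
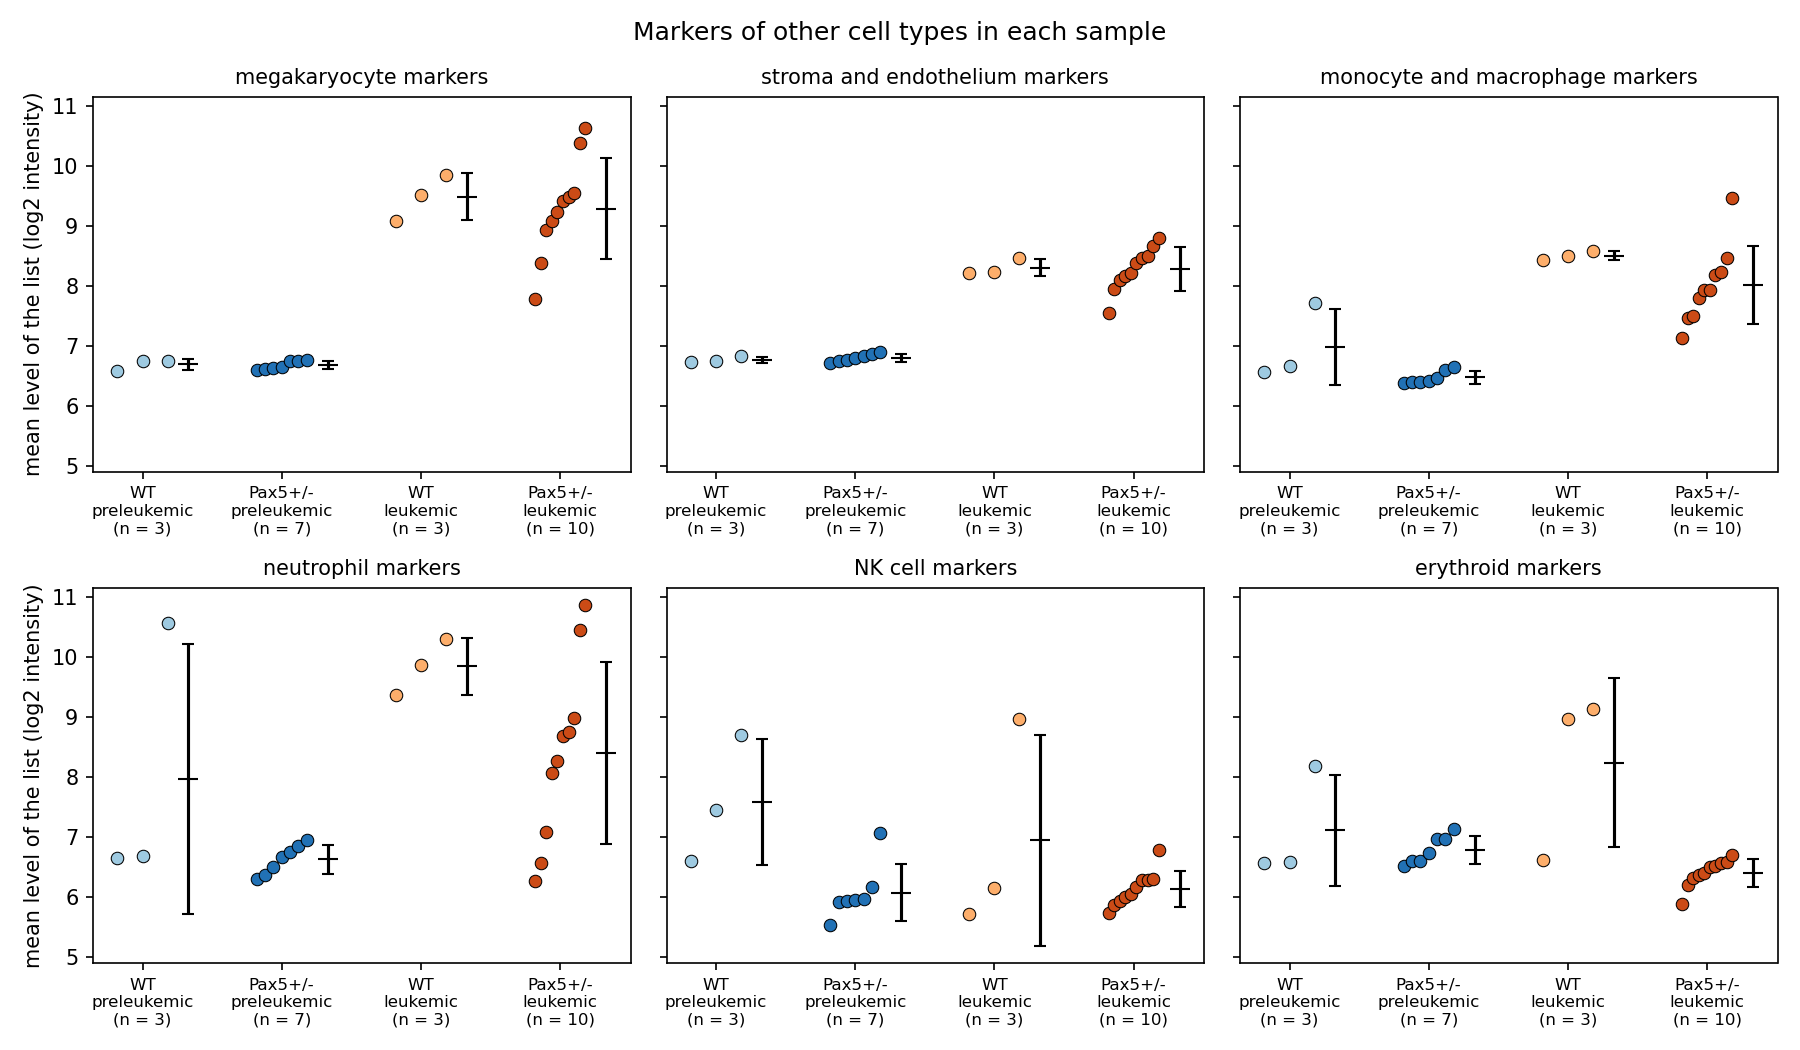
Mean level of each marker list (log2 intensity, vertical axis) per sample for 6 cell types, by group, points sorted by value within a group, with the group mean and SD as a black bar. Megakaryocyte and stroma markers were higher in every leukemia than in every preleukemic sample, and erythroid markers reached 8.97 and 9.15 in WT leukemias 15 and 17.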

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

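The tests of an even rise of all other cell types, of linked stretches of the genome, of an equal genotype difference in leukemia and of erythroid cells in WT leukemias 15 and 17 were chosen only after the result was seen.

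Leukemia 7 of the Pax5+/- mice stood apart from the other 9 leukemias in 9 of the 21 values that lay far from their group, out of 225 sets of values examined, where chance singles out about 1 in 20 sets, or 11.2. It was the highest for 4 genes that fell in leukemia, Cpm (9.12, others 5.41 to 7.11), Otub2 (8.42, others 5.47 to 5.77), Rag2 (8.89) and Smarca4 (11.4). It was the lowest for 5 genes that rose, Emb (7.72, others 10.01 to 11.45), Il18r1 (5.38, others 9.35 to 11.3), Atp8b4 (8.28), Grap2 (8.57) and Etv6 (9.73). It also held the highest Pax5 level of the leukemias. Each of these values lay on the side of the preleukemic cells.

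Other single samples lay far from their group relative to its range. Leukemia 3 was the lowest of 10 for Myc (9.07, others 11.17 to 11.95), Srm (9.22) and Apex1 (9.15). Leukemia 2 was the highest for Cd2 (8.3) and the lowest for Msh3 (7.31), and leukemia 4 was the lowest for Tyms (8.74). Leukemia 9 was the highest for Rad9a (9.4) and leukemia 10 the highest for Ermap (6.03, others 5.84 to 5.93). Pax5+/- preleukemic sample 12 was the highest of 7 for the mean of the NK cell markers (7.07, others 5.54 to 6.17) and the lowest for Spib (12.38) and Cth (5.12). Sample 24 was the highest of its group for Lpcat2 (6.16, others 5.84 to 5.9). For Cth the other samples held 5.47 to 5.72. The gaps of Ermap, Lpcat2 and Cth were small and lay below the highest array median of 6.2, so background could give them.

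The change from preleukemic to leukemic samples differed between the genotypes for 15 genes by the interaction test, as log2 change in Pax5+/- minus log2 change in WT. These were Dock9 (2.75), the cytokine gene Clcf1 (2.28), Edaradd (1.92), Slc1a5 (1.9), Klhl14 (1.67), Pacs2 (1.62), Bcat1, which acts on branched-chain amino acids (1.61), Tmc7 (1.56), the peptidase gene Enpep (1.23), Tmc6 (1.06), the deacetylase gene Hdac11 (0.92), Col5a3 (0.88), Fxyd6 (0.74), the nuclear pore gene Nup210 (0.58) and the growth kinase gene Mtor (0.53). All 15 were already lower in Pax5+/- than in WT cells before leukemia, a difference that the interaction contains.

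Markers of megakaryocytes, neutrophils, monocytes and stroma were higher in Pax5+/- leukemias than in preleukemic cells. Megakaryocyte markers rose by 2.99 more than erythroid markers on the log2 scale (2.987, exact permutation p = 5.14e-05, the smallest these samples allow). These lists were picked for their largest rise and their fall, so the p-value restates that choice. With medians over the members the erythroid fall did not pass. In every preleukemic sample 5 of 7 megakaryocyte but 3 of 8 erythroid markers lay above the array median, so background could limit their log2 changes unequally. The comparison thus cannot decide on a lower share of B cells that raised every other cell type alike. Varying shares of neutrophils, monocytes, megakaryocytes or platelets, and stroma stay open: members of these lists varied together across the 10 leukemias, with mean pairwise correlations of 0.834, 0.577, 0.943 and 0.352, each above the 95th percentile of random lists of like level. Expression of these markers by the leukemic cells themselves would also let members vary together and was not tested. No sort is stated for the leukemic samples, whose preleukemic partners were pro-B and pre-B cells.

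The differences of the 97 genes between Pax5+/- and WT preleukemic cells did not, as a set, depend on WT sample 20. Their median size without that sample was 1.035 of its size with it (0.861 against 0.832), and 67 of the 97 genes passed again. A gene raised by other cells in that sample alone would vary widely within its group and seldom pass. The choice of genes thus favoured this outcome. The median ratio of the leukemic to the preleukemic difference was 0.069 (95% bootstrap interval 0.022 to 0.148) over all 97 genes. It was 0.123 (0.032 to 0.248) over the 72 genes whose leukemic mean lay above every array median, with 3 genes over 0.5. The genes were chosen for their difference before leukemia, which lowers the ratio, and the bootstrap drew genes that share the same mice. The ratio thus cannot decide on a genotype or strain difference of equal size in every cell. Strain differences in linked stretches cannot be told apart from none: 7 of the genes had another among the 5 tested genes on either side, against a median of 6 and a 95th percentile of 12 in random sets, and the repair gene Xrcc1 was among the 7. The effect of the Pax5 genotype in B cell precursors stays open as the biological explanation, as does strain, also for single genes such as Ly86. Sex of the mice stays open in part, as the 3 WT preleukemic mice were Xist-low while Pax5+/- mice were mixed, and 87 genes passed with the Xist level as a covariate.

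Erythroid genes were lower in Pax5+/- than in WT leukemias. In WT leukemias 15 and 17 all 8 measured erythroid markers lay above the highest Pax5+/- leukemia, against 2 of 8 in WT leukemia 14. These 2 samples were picked for their high level of the same markers, so the count restates that choice. With 3 WT leukemias, erythroid cells in samples 15 and 17 cannot be told apart from a genotype difference in how much of the red cell lineage the marrow held, and both stay open.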

How the results depend on the processing

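Leaving out samples 15, 17 and 20 or leukemias 2, 6 and 7 together, and the single-sample runs of the cell type means, were chosen after seeing the data. Unless a sentence gives the construction, the cause was not tested. The count for Pax5+/- mice ranged from 9491 to 10170 with 1 sample left out. It fell to 3444 with the marker component, most of whose lists differed between the stages, as a covariate. Higher genes outnumbered lower genes there (2049 and 1395) and with the 50th percentile filter (4109 and 3684), against 4357 and 5677. The count for WT ranged from 3794 without sample 19 to 6902 without sample 20 (3828 without sample 18), and was 2353 with the marker component and 3537 with only the 2 groups in the fit, which estimates the spread from 6 arrays. The correlation of the stage changes ranged from 0.874 to 0.906 with 1 sample left out. The genotype difference before leukemia ranged from 40 genes without WT sample 19 to 137 without sample 20, and was 444 with array weights, which gave sample 20 the lowest weight, and 231 with only the 2 groups. The genotype difference in leukemia ranged from 0 genes without WT leukemia 15 to 160 without 14 (5 without 17), and was 127 with array weights, 21 with Xist as a covariate, 2 with the marker component, 1 with only the 2 groups and 9 without samples 15, 17 and 20. The interaction ranged from 6 genes without WT sample 19 to 98 without WT leukemia 14, 74 of them more negative in Pax5+/- mice (24 without Pax5+/- leukemia 7, 9 without WT leukemia 15, 36 without WT sample 20, 7 of them more negative), and was 82 with array weights, 32 of them more negative, 25 without samples 15, 17 and 20, 8 of them more negative, and 25 without leukemias 2, 6 and 7, 1 of them more negative. With all probe sets 2 of 19 were more negative, without Pax5+/- leukemia 7 or 9 2 each, and without Pax5+/- leukemia 3, Pax5+/- sample 12 or WT leukemia 17 1 each. The letter of the mouse number as a random block gave 10402 genes in Pax5+/- mice. Of 3 letters among leukemic and 2 among preleukemic samples 1 was shared, and the fitted block correlation was -0.032. That run thus could hardly separate the letter from the stage. Quantile normalization or centring moved no count by over 1.5 times.

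Gene lists passed in 14, 16, 8 and 11 cases in the 4 comparisons of groups, in the order given in the results. With an estimated correlation 0, 2, 0 and 1 passed, and with fry, which tests a list by itself, 24, 18, 0 and 1. With 1 sample left out, 7 (without WT sample 20) to 13 (without 19) lists passed between the genotypes before leukemia, and 5 (without WT leukemia 15) to 13 (without 17) in leukemia. The neutrophil list before leukemia had adjusted p from 2.32e-08 without WT sample 19 to 0.869 without sample 20, where it turned upward, and the plasmacytoid dendritic cell and monocyte lists had 0.869 there too. In leukemia the interferon list had adjusted p from 7.7e-08 to 0.103 and turned upward without WT leukemia 15 (3.19e-04), and the NK list had 3.94e-05 to 0.595 and turned upward without WT leukemia 15 (0.595).

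The Pax5 difference between the genotypes before leukemia ranged from -0.606 without WT sample 20 to -0.301 without 19, with an exact permutation p of 0.0556 without sample 18 or 19. In leukemia it ranged from -2.206 without WT leukemia 15, or -2.21 in limma (exact permutation p = 0.0455), to 0.024 without 17, or 0.02 in limma. The number of cell type lists whose means differed between stages in Pax5+/- mice was 8, and 6 with medians over the members, where erythroid (-0.005, adjusted p = 0.956) and T cell lists (0.17, 0.399) lost their call. Between the genotypes before leukemia it was 0 to 3 with 1 sample left out, 3 without Pax5+/- sample 12, and 2 with medians over the members, and in leukemia 0 to 1, 1 without Pax5+/- leukemia 6. With 1 sample left out, all 76 passing genes named for Pax5+/- leukemia and all 5 named for the interaction kept their call. In WT leukemia 30 of 33 did, the others being Pax5, Xist and Eif2s3y. Before leukemia 13 of 21 did, the others being Apobec3, Lpcat2, Gtse1, Gfod1, Prxl2c, Fmn2, Ocel1 and Xrcc1. In leukemia 0 of 16 did, with adjusted p of 0.17 for Ly86 and of up to 0.68 for the others without WT leukemia 15. The WT log2 differences of Xist (6.82 to 7.05) and Eif2s3y (-4.75 to -4.67) hardly moved in these runs. Their spread was estimated over all groups, and both Pax5+/- groups held Xist-high and Xist-low samples. Folds of named genes moved by over 1.5 times with 1 sample left out for 1 of 76, 6 of 33, 1 of 21, 10 of 16 and 0 of 5 genes, in the 4 comparisons of groups and the interaction, in the order of the results. Array signal near background limits how far falls to, or rises from, low levels can be measured.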

Other observations

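The 10 Pax5+/- leukemias differed widely in markers of other lineages. The mean of the megakaryocyte markers ran from 7.79 in leukemia 9 to 10.63 in leukemia 4, while leukemia 4 had the lowest neutrophil mean, 6.27, and leukemia 6 the highest, 10.87. Monocyte markers ran from 7.13 in leukemia 9 to 9.47 in leukemia 2, and stroma markers from 7.55 in leukemia 9 to 8.8 in leukemia 2. The second principal component, with 8.12% of the variance, put leukemia 2 at 42.72.

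The tests of a shift toward leukemia were chosen only after the result was seen. A hypothesis was that a higher Pax5 level goes with higher PAX5-activated genes and lower PAX5-repressed genes across these 10 leukemias, and that interleukin-7 and JAK-STAT genes go against pre-B cell receptor genes, 3 relations in all. Pax5 and the PAX5-activated mean had r = 0.195 (permutation p = 0.626, adjusted p = 0.626) and rho = 0.055 (permutation p = 0.893), and r = -0.121 without leukemias 7 and 2. Pax5 and the PAX5-repressed mean had r = -0.748 (permutation p = 0.0679, adjusted p = 0.204) and rho = -0.115 (permutation p = 0.759), and r = 0.596 without leukemias 7 and 2, so the relation rests on those samples. The interleukin-7 and pre-B cell receptor means had r = -0.48 (permutation p = 0.162, adjusted p = 0.243) and rho = -0.382 (permutation p = 0.279), and r = -0.117 without leukemias 4 and 7. None of the 3 relations passed, and 10 samples leave them open.

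A further hypothesis was that genes lower in Pax5+/- than WT preleukemic cells may already be moving toward the leukemic state. Of 35 genes called with Pax5+/- samples 21 to 24, 8 fell again and 6 rose from samples 11 to 13 to leukemia, against a median of 8 falls in random gene sets of like level. Of 32 genes called with samples 11 to 13, 14 fell again and 2 rose from samples 21 to 24, against a median of 11 falls and a 95th percentile of 15. Of 20 higher genes called with samples 21 to 24, 3 rose again and 13 fell, against a median of 4 rises in random sets. Of 18 called with samples 11 to 13, 3 rose again and 8 fell, against a median of 5 rises. None of the counts of genes that moved again separates a shift from none. In both runs more of the higher genes fell than rose toward leukemia, and random sets were not drawn for these falls.

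Regrouping the samples asked whether chance could give as many genes. In Pax5+/- mice 1 of 100 splits, the real one, gave as many as the 10034 genes between stages, and the highest other split gave 1. Between the genotypes before leukemia 1 of 100 splits gave as many as 97, with 26 in the highest other. These 2 shares exclude chance at 0.05. For the interaction 2 of 100 gave as many as 15, with 39 in the highest other. Its splits regrouped the genotypes at both stages, so they also broke up the genotype difference before leukemia that the interaction contains. That share therefore cannot exclude chance for the interaction itself. In WT mice 3 samples against 3 make 10 splits, too few for a share under 0.05, and the real split, 1 of 10, gave 5780 genes against 104 in the highest other. Between the leukemias of the genotypes 4 of 100 splits, drawn from 286, gave as many as the 53 genes. That share lies too near 0.05 to exclude chance, as most splits were not drawn and 0 genes passed without WT leukemia 15. The highest other split, which set Pax5+/- leukemias 9 and 10 with WT leukemia 14, gave 200, and the cause was not tested.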
